A study of Mus musculus with 12 samples.

How the data were processed

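RNA was measured by sequencing in whole mouse lungs of embryonic day 15.5, of strain C57BL/6 per the labels, in 2 groups of 3 lungs, WT and CKO. Per the labels' protocols, the animals came from crosses of floxed Tgfbr2 mice with mice carrying Tbx4-rtTA and TetO-Cre, and doxycycline was given from E6.5 in food and at 1 mg/ml in drinking water. Frozen lungs were extracted with Trizol and an RNeasy Micro kit, and libraries were made with Illumina TruSeq v2. Each lung was sequenced in 2 runs that share 1 replicate label, and groups and replicate numbers were taken from the labels.

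The authors trimmed reads with cutadapt 1.13 and Trimmomatic 0.35, aligned them with STAR 2.5.2b to GRCm38 and counted them with HTSeq 0.6.1p2, per the submitters' processing notes, and the annotation was GENCODE M8, per the file headers. The deposited gene table holds raw counts for each run of each lung, whole numbers that are not normalised. Whether the counting used strand is not given in the sources used here. Beside each count column the authors deposited RPKM, reads per kilobase scaled to library size, whose scale is an effective library size of 0.982 to 1.01 times the column total. Over the 19931 genes whose isoforms share exon sequence, the length behind the RPKM was compared with the annotation used here. It was a median of 1.60 times the length of the merged exons and 1.00 times the exons summed over isoforms. A deposited table of the authors' comparison gives a log2 fold change, a p-value and an adjusted p-value per gene from edgeR (3.16.5 per the submitters' processing notes); how the 2 runs entered that fit is not given in the sources used here. A deposited alignment table gives counts of reads per run, from which the shares of reads outside annotated features were taken. The comparison table also carries 24 columns of per-sample values beside its test results, and these were not used.

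The table has 47161 entries, of which 92 are ERCC spike-ins and 47069 are genes, 30341 of them with at least 1 count. Spike-ins took 0.498% to 0.595% of all counts and were left out of library sizes and tests. The 2 runs of a lung were summed. Per lung, the chi-square per degree of freedom between its runs was 1.42 to 1.50 over genes with at least 20 counts, against 8.46 to 45.6 between lungs of a group.

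Counts were tested with edgeR 4.0.16 (quasi-likelihood fit and F test, TMM scaling, filterByExpr with a minimum count of 10) in R 4.3.3, with group as the single factor over all 6 lungs and Benjamini-Hochberg adjustment; calls are genes with an adjusted p under 0.05. CPM use the TMM-scaled library sizes. The common biological coefficient of variation was 0.127. Gene positions come from GENCODE M21, which uses the same assembly; 98.8% of the genes matched by identifier, all on the same chromosome. With 2 groups of 3 lungs, precision rests on the spread between lungs more than on depth.

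Before the data were examined, 36 gene lists, the tests, their design and the rule for named genes were fixed. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and again with an estimated correlation, adjusted over the 36 lists; with the estimated correlation 0 lists passed, and 2 had an unadjusted p under 0.05 (neuroendocrine cells and p53 targets). For each list, the text gives the members that rose, fell or did not pass, and the counts adjusted over the list alone. Lists share some members, such as Acta2, Hhip, Tcf21, Wnt2, Wnt2b, Bmp4, Etv4 and Etv5, and many of the marker genes are made by more than 1 cell type of the lung.

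Named genes are Tgfbr2; the 12 with the largest log2 fold change in each direction among called genes with a mean of at least 1 CPM, no overlap between groups and no predicted-gene symbol; and up to 4 tested members of each list with the smallest p. Other genes are named to spell out small counts or to follow the lists: Des, Fn1, Eln, Tgfbi, Bambi, Loxl1, Bgn, Sox2, Foxj1, Wnt2b, Dkk3, Bmpr1b, Gas1, Jag1, Gm3608, Gm6969 and the other genes that are on in some lungs and off in others. These were chosen after their values were seen. Among the genes that the rule selects, those that overlap another annotated gene with a sizeable count beside theirs are said to do so. The genes chosen after their values were seen were not checked for overlap. Some genes counted among the members or selected by the rule are not reported here.

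The procedure was tested on simulated counts drawn from the means and library sizes of these lungs, with 200 changed genes, of which some fell under the low-count filter; 17567 genes were tested, 17373 of them unchanged. For this comparison, over changed genes tested or not, it recovered 46.3% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 86.4% of those changed 4-fold, and made 9 false calls among the unchanged genes. Counts were drawn for each gene on its own, with no lung that shifts many genes together. These rates therefore need not hold where many genes of a lung shift together.

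Alternatives fixed before the data were examined were DESeq2 size factors, total count scaling, no filter on low counts, a filter of at least 1 CPM in all lungs of either group, DESeq2 1.42.0, limma-voom, limma on log2 of RPKM plus 1 or plus 0.1 (fold changes on that scale understate the change of low genes), the replicate number as a block, each run alone, erythroid and mitochondrial genes left out, a test against a fold change of 1.2, and each lung left out in turn. After the data were examined, replicate 1 as a covariate, replicates 2 and 3 only, and the share of reads outside annotated features as a covariate were added. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.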

Results

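RNA-seq was carried out on whole mouse lungs at embryonic day 15.5 (E15.5), with 3 wild-type (WT) and 3 conditional knockout (CKO) lungs as the labels number them. In the CKO lungs a floxed Tgfbr2, which encodes the type II receptor for transforming growth factor beta (TGF-beta), was combined with a Tbx4-driven, doxycycline-dependent Cre that acts in lung mesenchyme, and doxycycline was given from E6.5. The gene counts summed to 31983717, 51572845 and 45057871 in WT replicates 1 to 3 and to 40214017, 36741615 and 41680516 in CKO replicates 1 to 3. Values are normalised read counts scaled to effective library size (CPM), as mean ± SD with n = 3 lungs per group. The labels do not say whether the lungs of a group share a litter, and p-values measure the spread between these lungs.

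The libraries differed in ways the groups do not name. Reads outside annotated features made up 16.1%, 15.3% and 14.5% of uniquely mapped reads in the WT lungs and 17.0%, 11.8% and 12.8% in the CKO lungs, and genes that collect ribosomal RNA reads made up 1.68%, 1.21% and 0.812% against 1.65%, 0.366% and 0.393% of gene counts. Xist, the RNA that coats the inactive X chromosome, had 61807 counts in WT replicate 1 and 100817 in CKO replicate 1 against 22 to 41 in the other lungs. The Y chromosome genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 to 2 counts in replicate 1 of both groups and 1487 to 4387 in the other lungs. By these counts replicate 1 of both groups was female and the other lungs were male, so CKO replicate 1 was the only female CKO lung. On the leading principal component, which held 54.1% of the variance, the WT lungs lay at -34.4, -31.1 and -28.1, CKO replicate 1 at -2.41, and CKO replicates 2 and 3 at 45.3 and 50.8.

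The targeted gene, Tgfbr2 (ENSMUSG00000032440, chromosome 9, 116084293 to 116175360, GRCm38, minus strand), was counted at similar levels in all 6 lungs. It had 199.7, 203 and 230.0 CPM in WT replicates 1 to 3 and 213, 221 and 239 CPM in CKO replicates 1 to 3. The group values were 211 ± 16.7 and 225 ± 13.1 CPM (log2 fold change 0.09 ± 0.07 SE, adjusted p = 0.453), a difference within the spread between lungs. The count covers the whole gene in the whole lung, with the cells in which Cre does not act, and the position of the floxed part is not given in the sources used here. It therefore checks nothing about the deletion, and the group labels rest on the submitters' genotypes.

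The comparison of CKO with WT lungs asks which genes of the whole lung differ when the receptor gene is targeted in the mesenchyme. Of 9 tested genes of secretory and basal airway epithelium 4 fell in the CKO lungs, of 10 neuroendocrine genes 3 fell and 1 rose, and of 18 smooth muscle genes 8 fell and 1 rose; Krt15, Insm1 and Acta2 fell 9.40-fold, 8.65-fold and 1.89-fold. Of 17 genes of myeloid and other immune cells, 19 of endothelium and 13 of red blood cells, 11, 11 and 5 rose, with Csf1r 1.73-fold and Emcn 1.63-fold higher, and the WNT antagonist Dkk1 rose 121-fold. Each of these 6 lists passed camera with a preset correlation and did not with an estimated correlation (adjusted p = 0.520 to 0.570). Insm1 and Emcn passed with any 1 lung left out (highest adjusted p 0.0245 for both), though Insm1 was low, at 1.03 CPM in WT and 0.116 CPM in CKO lungs. Acta2 did not without WT replicate 1 (0.0649), WT replicate 2 (0.0774) or CKO replicate 2 (0.0825), nor Csf1r without these (0.0709, 0.0930 and 0.0926) or CKO replicate 3 (0.0665), nor Dkk1 without WT replicate 1 (0.0545) or 2 (0.0669). Krt15 had a log2 fold change of -5.41 without CKO replicate 1 and did not pass without any other 1 lung (0.0592 to 0.154). Of 17843 genes tested with edgeR's quasi-likelihood test at an adjusted p under 0.05, 1006 were higher and 549 lower in the CKO lungs, and 298 and 160 of these differed at least 2-fold. The CPM of the 2 groups did not overlap for 5337 genes, 29.9% of those tested, where chance alone gives 10%.

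These counts depended on single lungs. Without CKO replicate 1, 1713 genes were higher and 1185 lower, and 1519 of the 1555 calls were kept. Leaving out WT replicate 1 gave 264 higher and 130 lower, WT replicate 2 gave 162 and 90, CKO replicate 2 gave 211 and 90, and CKO replicate 3 gave 325 and 157; no gene called with all 6 lungs changed sign in any of these fits. Of the 112 called genes that the fixed naming rule selects besides Tgfbr2, 66 lost their call without WT replicate 1, 80 without WT replicate 2, 10 without WT replicate 3, 1 without CKO replicate 1, 71 without CKO replicate 2 and 43 without CKO replicate 3. In each gene list with 1 to 5 called members, 0 to 4 were called when WT replicate 1, WT replicate 2, CKO replicate 2 or CKO replicate 3 was left out.

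Among the 12 genes with the largest rises, Dkk1 (ENSMUSG00000024868, chromosome 19, 30545863 to 30549665) rose from 0.419 ± 0.0807 to 49.7 ± 37.9 CPM (log2 fold change 6.92 ± 1.04 SE, adjusted p = 0.0103). Its CKO lungs ranged widely, with 6.28 CPM in replicate 1, 66.6 in replicate 2 and 76.3 in replicate 3. Isl1, a LIM homeodomain transcription factor, rose 14.7-fold to 21.6 ± 13.5 CPM, with 6.43 CPM in CKO replicate 1. Pax7, a transcription factor of muscle precursor cells, rose from 0.0434 ± 0.0376 to 4.31 ± 3.32 CPM, and the myosin heavy chain genes Myh7b and Myh8 rose 9.58-fold and 8.84-fold. Insrr, an insulin receptor relative, rose 17.0-fold. Insrr overlaps Pear1, and Myh7b overlaps Trpc4ap, so these values are uncertain where the counting could not part the genes. Others were the homeobox gene Irx6 (log2 fold change 5.17), the opioid precursor Pdyn (4.59), the actin-severing protein gene Scin (4.13), Elfn1 (3.59) and the matrix protein vitronectin, Vtn (3.25). Of these 12 genes, 9 did not pass without WT replicate 1, 10 without WT replicate 2, 6 without CKO replicate 2, 3 without CKO replicate 3 and 1, Scin, without WT replicate 3 (adjusted p = 0.0501 to 0.156). Leaving out WT replicate 3 gave log2 fold changes of 5.06 for Insrr, 7.29 for Pax7 and 3.95 for Vtn, WT replicate 2 gave 5.98 for Pax7 and CKO replicate 3 gave 3.88 for Pdyn. With the share of reads outside annotated features as a covariate, chosen after the data were examined, the log2 fold changes of Dkk1, Pax7, Irx6, Pdyn, Scin, Isl1, Elfn1, Myh7b and Myh8 were 5.44, 5.09, 4.25, 3.77, 2.37, 3.05, 2.83, 2.61 and 2.49, against 6.92, 6.66, 5.17, 4.59, 4.13, 3.88, 3.59, 3.26 and 3.14. Limma-voom gave 6.24 for Dkk1, 6.08 for Pax7 and 3.23 for Scin. With 1 lung left out the adjusted p of Dkk1 ranged from 1.39e-07 to 0.0669 and that of Isl1 from 9.26e-06 to 0.0631; without WT replicate 1 these were 0.0545 and 0.0502 and without WT replicate 2 they were the highest.

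The largest fall was that of Nr1h5 (ENSMUSG00000048938, chromosome 3, 102939658 to 102964133), a nuclear receptor gene of the farnesoid X receptor family, from 16 ± 3.0 to 0.0663 ± 0.0250 CPM (log2 fold change -7.84 ± 0.27 SE, adjusted p = 2.69e-05). The airway genes Krt15, a basal keratin, Cyp2f2, a cytochrome P450 of club cells, and Sox21 fell 9.40-fold, 8.02-fold and 8.89-fold. Pthlh, which encodes parathyroid hormone-like hormone, fell 5.69-fold from 6.59 ± 0.316 CPM, and Ret, a receptor tyrosine kinase gene of enteric and other neurons, fell 4.70-fold from 8.24 ± 1.23 CPM. Falls of 4.93-fold to 6.58-fold were seen for Cps1, Miat, Tacr1, Smpx and Tnfsf13b. Without CKO replicate 1 the log2 fold changes were -5.41 for Krt15, -4.85 for Cyp2f2, -4.07 for Sox21, -4.08 for Cps1, -3.69 for Smpx, -3.15 for Pthlh, -3.02 for Ret and -2.91 for Tnfsf13b, against -3.23, -3.0, -3.15, -2.72, -2.36, -2.51, -2.23 and -2.30 with all lungs. Of the 12 genes with the largest falls, 8 did not pass without WT replicate 1, WT replicate 2 or CKO replicate 2, 7 without CKO replicate 3 and 3 without WT replicate 3 (adjusted p = 0.0513 to 0.161), Smpx among them each time. Limma-voom gave -4.29 for Krt15 and -3.74 for Cyp2f2, and 1 of the 2 runs alone gave -8.55 for Nr1h5, -3.33 for Cps1 and -2.97 for Tacr1. CKO replicate 1 was at 3.14 CPM for Krt15 and 3.71 CPM for Cyp2f2, against 0.405 and 0.432 CPM in CKO replicate 2 and 0.142 and 0.404 CPM in CKO replicate 3. Without each of WT replicates 1, 2 and 3 and CKO replicates 2 and 3, the adjusted p of Krt15 was 0.128, 0.134, 0.0592, 0.154 and 0.0744 and that of Cyp2f2 was 0.124, 0.117, 0.0635, 0.136 and 0.101; without CKO replicate 1 they were 3.74e-05 and 3.19e-05.

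**Figure D1:**
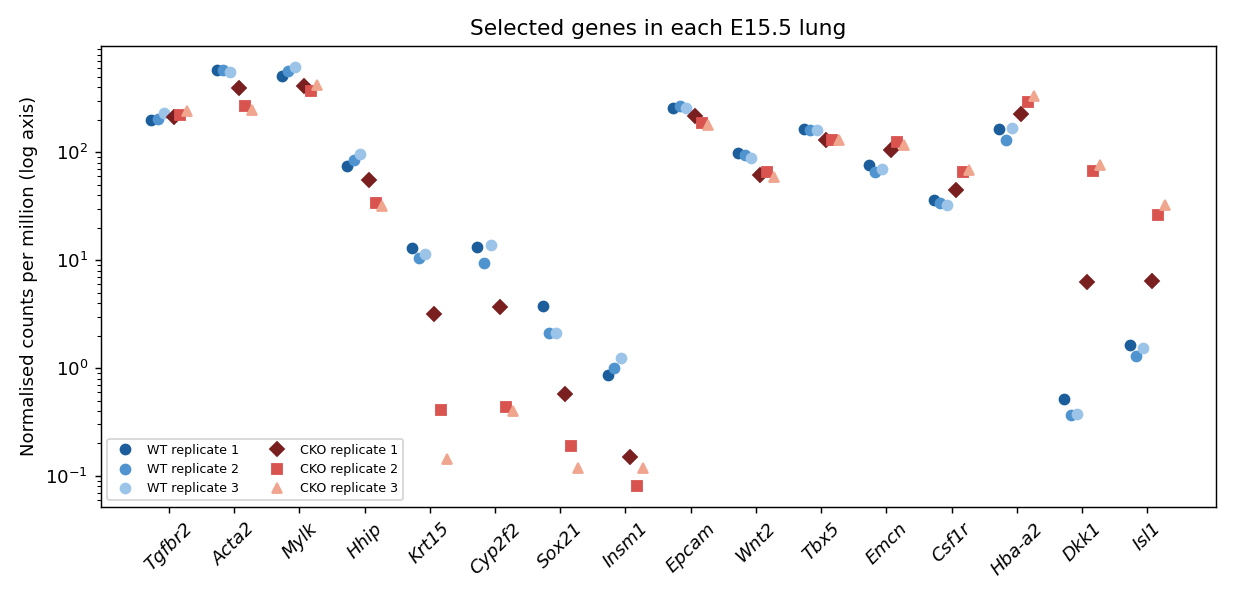
Normalised CPM (log axis) of 16 genes in each lung, with circles for WT and diamonds, squares and triangles for CKO replicates 1, 2 and 3. Tgfbr2 lies at 199.7 to 239 CPM in all 6 lungs, and CKO replicate 1 lies between the WT lungs and the other CKO lungs for genes such as Acta2, Krt15 and Dkk1.

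Smooth muscle genes were lower in the CKO lungs. Of 18 tested members, 8 fell, 1 rose and 9 did not pass; adjusted over the list alone, 13 fell and 1 rose (camera adjusted p = 4.96e-06 for a fall, adjusted p = 0.570 with an estimated correlation). Acta2, smooth muscle actin, fell 1.89-fold from 571 ± 18.7 to 303 ± 77.9 CPM (adjusted p = 0.0169), Mylk, the myosin light chain kinase gene, fell 1.41-fold from 566 ± 53.9 CPM, Tpm1 fell 1.24-fold from 594 ± 6.16 CPM, and Hhip, a Hedgehog-binding protein gene, fell 2.12-fold from 85.3 ± 11.2 CPM. The member that rose was Des, the intermediate filament gene desmin, at 1.26-fold (named after its value was seen). The shift of Acta2 in CKO replicate 1 was 57.1% of that in CKO replicates 2 and 3. Without CKO replicate 1, 15 members fell; without WT replicate 1, WT replicate 2, CKO replicate 2 or CKO replicate 3, 0 to 2 fell.

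Genes of the TGF-beta pathway and its targets went both ways. Among 15 tested pathway components 1 rose, 2 fell and 12 did not pass, and adjusted over the list alone 5 rose and 2 fell (camera adjusted p = 0.444). Leaving out WT replicate 3 gave 5 that rose and 2 that fell, and CKO replicate 1 gave 4 and 2. Leaving out CKO replicate 3 gave 0 and 2, and any other single lung gave 0 and 0. Acvrl1, a type I receptor gene of endothelium, rose 1.40-fold, Smad3, a signal transducer, fell 1.22-fold and the ligand gene Tgfb3 fell 1.49-fold, while the ligand gene Tgfb1 had CPM 28.7 ± 0.427 in WT and 36.5 ± 4.52 in CKO lungs (adjusted p = 0.0584); Tgfb3 overlaps Ttll5. Among 22 tested TGF-beta target genes 3 rose, 5 fell and 14 did not pass; adjusted over the list alone, 6 rose and 12 fell. Pmepa1, a feedback inhibitor, fell 1.97-fold from 48.3 ± 2.05 CPM, as did Acta2, and the cell cycle inhibitor Cdkn2b rose 4.72-fold and the protease inhibitor Timp3 1.77-fold. Fn1 also rose (1.49-fold), and Eln, Tgfbi and Bambi also fell (2.99-fold, 2.13-fold and 1.36-fold), all 4 named after their values were seen. The target list did not pass camera (adjusted p = 0.0526 for a fall) with all lungs and passed without WT replicate 1 (0.0475), WT replicate 2 (0.0424) or CKO replicate 1 (0.0124), in a range of 0.0124 to 0.179 with 1 lung left out. It also passed with total count scaling (0.0366) and, in tests chosen after the data were examined, with replicate 1 (0.0472) or the share of reads outside annotated features (0.0126) as a covariate and with replicates 2 and 3 only (0.00956); with an estimated correlation it did not (adjusted p = 0.570). The target genes called were 5 higher and 10 lower without CKO replicate 1, 0 and 1 without WT replicate 1, WT replicate 2 or CKO replicate 2, and 2 and 2 without CKO replicate 3.

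Matrix genes also went both ways. Among 28 tested members of the fibrillar and elastic matrix list 8 rose, 4 fell and 16 did not pass; adjusted over the list alone, 10 rose and 7 fell (camera adjusted p = 0.506). The small leucine-rich proteoglycan genes Lum and Dcn rose 2.40-fold to 96.5 ± 19.1 CPM and 2.08-fold to 231 ± 38.2 CPM, and Col14a1 rose 1.53-fold. Mfap2, a microfibril gene, fell 1.31-fold; Eln, which encodes elastin, fell from 608 ± 104 to 203 ± 95.1 CPM, and Loxl1 and Bgn fell 1.29-fold and 1.30-fold (these 3 named after their values were seen). Of 16 tested cartilage genes 2 rose, 1 fell and 13 did not pass; adjusted over the list alone, 2 rose and 2 fell (camera adjusted p = 0.174). Matn4 and Col9a3 rose 1.88-fold and 1.45-fold and Col9a2 fell 1.55-fold; Matn4 overlaps Rbpjl. Without CKO replicate 1, 7 cartilage genes fell and the list passed camera (adjusted p = 0.0124, in a range of 0.0124 to 0.377 with 1 lung left out). Of the matrix genes, 2 rose and 2 fell without WT replicate 1, 3 and 1 without CKO replicate 3, and 2 rose without WT replicate 2 or CKO replicate 2.

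Conducting airway genes had the lowest median log2 fold change of the 36 lists, -2.43 for secretory and basal airway epithelium. All 4 secretory and basal airway genes that passed, of 9 tested, fell, and 5 did not pass; adjusted over the list alone, 9 fell (camera adjusted p = 1.23e-05, adjusted p = 0.570 with an estimated correlation). These were Krt15, Cyp2f2, Sox21, with CPM 2.65 ± 0.944 in WT and 0.294 ± 0.244 in CKO lungs, and Upk3a, a uroplakin of a club cell subset, with CPM 1.41 ± 0.674 in WT and 0.117 ± 0.180 in CKO lungs; Sox21 overlaps Gm4675. The log2 fold changes of Krt15, Cyp2f2, Sox21 and Upk3a without CKO replicate 1 were -5.41, -4.85, -4.07 and -6.50, against -3.23, -3.0, -3.15 and -3.57 with all lungs, and that of Upk3a was -2.96 without CKO replicate 3. With limma-voom those of Krt15, Cyp2f2 and Upk3a were -4.29, -3.74 and -4.64. Sox2, the transcription factor of proximal airway, had CPM 14.6 ± 1.59 in WT and 2.69 ± 3.30 in CKO lungs (adjusted p = 0.0731; named after its value was seen). Of the secretory and basal genes, 8 fell without CKO replicate 1; without any other single lung, 0 to 2 fell. The lungs farthest from WT in these genes, CKO replicates 2 and 3, also had the lowest shares of reads outside annotated features, 11.8% and 12.8%.

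Among 21 tested genes of ciliated cells 1 rose, 1 fell and 19 did not pass; adjusted over the list alone, 2 rose and 1 fell (camera adjusted p = 0.00226 for a fall, adjusted p = 0.758 with an estimated correlation). Tekt1, a microtubule protein gene of cilia, fell 1.92-fold and Tppp3, a tubulin polymerization gene, rose 2.79-fold to 62.3 ± 19.6 CPM. The ciliated cell regulator Foxj1, named after its values were seen, had 10.2, 8.41 and 28.1 CPM in the WT lungs and 8.49, 0.459 and 0.736 CPM in the CKO lungs (adjusted p = 0.185). The list's camera result did not pass without WT replicate 3 (adjusted p = 0.0693, the highest with 1 lung left out), and its calls varied with the lung left out: 12 of these genes fell and 2 rose without CKO replicate 1, 3 rose and 0 fell without WT replicate 3, 1 rose and 0 fell without CKO replicate 3, and none passed without WT replicate 1, WT replicate 2 or CKO replicate 2.

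Of 10 tested neuroendocrine genes 3 fell, 1 rose and 6 did not pass; adjusted over the list alone, 4 fell and 1 rose (camera adjusted p = 0.0191, adjusted p = 0.520 with an estimated correlation). The transcription factor gene Insm1 fell 8.65-fold, from 1.03 ± 0.188 to 0.116 ± 0.0343 CPM. The prohormone convertase gene Pcsk1 fell 11.7-fold, from 1.11 ± 0.272 to 0.0916 ± 0.0509 CPM. Both folds rest on low counts. Cplx2, a gene of synaptic vesicle release, rose 1.78-fold from 78.4 ± 1.85 CPM. With any 1 of the 6 lungs left out, 3 members were lower and 1 higher.

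Of 19 tested general epithelial genes 8 fell and 11 did not pass; adjusted over the list alone, 12 fell (camera adjusted p = 5.27e-05, adjusted p = 0.570 with an estimated correlation). The forkhead genes Foxa2 and Foxa1 fell 1.51-fold and 1.32-fold, Epcam, an epithelial adhesion molecule, fell 1.35-fold from 262 ± 8.13 to 194 ± 20.2 CPM, and the tight junction gene Cldn4 fell 1.27-fold. Without WT replicate 1, WT replicate 2, WT replicate 3, CKO replicate 2 or CKO replicate 3, 1, 1, 5, 0 and 2 of them fell. The distal lists held no such common direction: of 17 tested distal tip and type 2 genes 1 rose, 3 fell and 13 did not pass; adjusted over the list alone, 2 rose and 6 fell (camera adjusted p = 0.151). Bmp4, a growth factor gene, rose 1.96-fold to 153 ± 41.1 CPM, and the transcription factor genes Etv4, Etv5 and Sox9 fell 1.79-fold, 1.68-fold and 1.17-fold. Of 13 tested type 1 epithelium genes 1 rose, 1 fell and 11 did not pass, and adjusted over the list alone 5 rose and 4 fell (camera adjusted p = 0.706). Leaving out WT replicate 3 gave 5 that rose and 1 that fell, and CKO replicate 1 gave 4 and 4. Leaving out CKO replicate 3 gave 0 and 1, and any other single lung gave 0 and 0. Emp2 rose 1.97-fold, Igfbp2 fell 3.0-fold and Ager, a type 1 cell marker, had CPM 63.7 ± 18.3 in WT and 107 ± 17.9 in CKO lungs (adjusted p = 0.0576).

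Among 18 tested regulators of lung mesenchyme 2 rose, 6 fell and 10 did not pass, and adjusted over the list alone the counts were the same, 2 and 6 (camera adjusted p = 0.444). The growth factor gene Wnt2 fell 1.51-fold from 94.1 ± 5.84 to 62.2 ± 3.76 CPM, the platelet-derived growth factor receptor gene Pdgfra fell 1.35-fold and the T-box gene Tbx5 fell 1.24-fold from 160.5 ± 2.05 to 129.8 ± 0.930 CPM. Tcf21, a transcription factor of lung fibroblasts, rose 1.61-fold to 212 ± 24.6 CPM, and Wnt2b rose 1.92-fold (named after its value was seen). Without CKO replicate 2, 1 regulator rose and 3 fell, and without WT replicate 2, 2 rose and 3 fell. Of 9 tested lipofibroblast genes 2 rose, 1 fell and 6 did not pass; adjusted over the list alone, 5 rose and 1 fell (camera adjusted p = 0.0922, and 0.0249 without CKO replicate 1, in a range to 0.172 with 1 lung left out). Fabp4, a fatty acid binding protein gene, rose 4.54-fold from 0.823 ± 0.455 CPM, as did Tcf21, and the lipoprotein lipase gene Lpl fell 1.41-fold. Of 11 tested pericyte genes 2 rose and 9 did not pass; adjusted over the list alone, 2 rose (camera adjusted p = 0.0526, and 0.0136 without WT replicate 3, in a range to 0.143 with 1 lung left out). Cox4i2, a subunit of cytochrome oxidase, rose 1.84-fold, the guanylate cyclase gene Gucy1b3 rose 1.29-fold, and Pdgfrb had CPM 218 ± 20.3 in WT and 256 ± 15.4 in CKO lungs (adjusted p = 0.108).

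Genes of myeloid and other immune cells were higher in the CKO lungs. Of 17 tested members 11 rose and 6 did not pass; adjusted over the list alone, 17 rose (camera adjusted p = 6.38e-08, adjusted p = 0.570 with an estimated correlation). The complement genes C1qa and C1qc rose 1.76-fold and 1.69-fold, the receptor gene Csf1r of macrophages rose 1.73-fold from 34.2 ± 1.5 to 59.3 ± 13 CPM, and the pan-leukocyte gene Ptprc rose 1.91-fold; Csf1r overlaps Hmgxb3. CKO replicate 1 had 44.4 CPM of Csf1r against 65.5 and 68.0 CPM in CKO replicates 2 and 3. CKO replicates 2 and 3 also had the lowest shares of reads outside annotated features, 11.8% and 12.8%. Without CKO replicate 1, 17 rose, without WT replicate 3, 6 rose, and without WT replicate 1, WT replicate 2, CKO replicate 2 or CKO replicate 3, 0 or 1 rose.

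Of 19 tested endothelial genes 11 rose and 8 did not pass; adjusted over the list alone, 16 rose (camera adjusted p = 3.32e-07, adjusted p = 0.570 with an estimated correlation). Emcn, an endothelial sialomucin gene, rose 1.63-fold from 70.9 ± 5.83 to 115 ± 8.71 CPM (adjusted p = 0.00382), the vascular growth factor receptor gene Kdr rose 1.36-fold from 245 ± 13.9 CPM, and Esam and Egfl7 rose 1.24-fold and 1.24-fold; Egfl7 overlaps Agpat2. Without CKO replicate 1, 14 rose, without WT replicate 2, 2 rose, and without WT replicate 1, CKO replicate 2 or CKO replicate 3, 5 rose. Of 5 tested lymphatic endothelium genes 1 rose, 1 fell and 3 did not pass; adjusted over the list alone, 2 rose and 3 fell (camera adjusted p = 0.633). Prox1, the lymphatic transcription factor gene, fell 2.09-fold from 7.12 ± 0.616 CPM and the hyaluronan receptor gene Lyve1, also made by macrophages, rose 1.32-fold.

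Red blood cell genes were also higher. Of 13 tested erythroid genes 5 rose and 8 did not pass; adjusted over the list alone, 9 rose (camera adjusted p = 0.000187, adjusted p = 0.520 with an estimated correlation). The globin genes Hba-a1, Hba-a2 and Hbb-bs rose 1.87-fold, 1.84-fold and 1.71-fold, and the anion exchanger gene Slc4a1 rose 1.39-fold. The globin genes have near-identical copies, so which copy rose is uncertain. Of the erythroid genes, 8 rose without CKO replicate 1; without WT replicate 1, WT replicate 2, CKO replicate 2 or CKO replicate 3, 0 or 1 rose. Of 10 tested mesothelial genes 2 rose and 8 did not pass; adjusted over the list alone, 4 rose (camera adjusted p = 0.0288, adjusted p = 0.570 with an estimated correlation). Upk3b, a mesothelial marker, rose 1.64-fold to 82.8 ± 9.11 CPM, and Gpm6a rose 1.27-fold. The mesothelial result did not pass without WT replicate 2 (adjusted p = 0.0735), WT replicate 3 (0.0769) or CKO replicate 3 (0.0524).

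**Figure D2:**
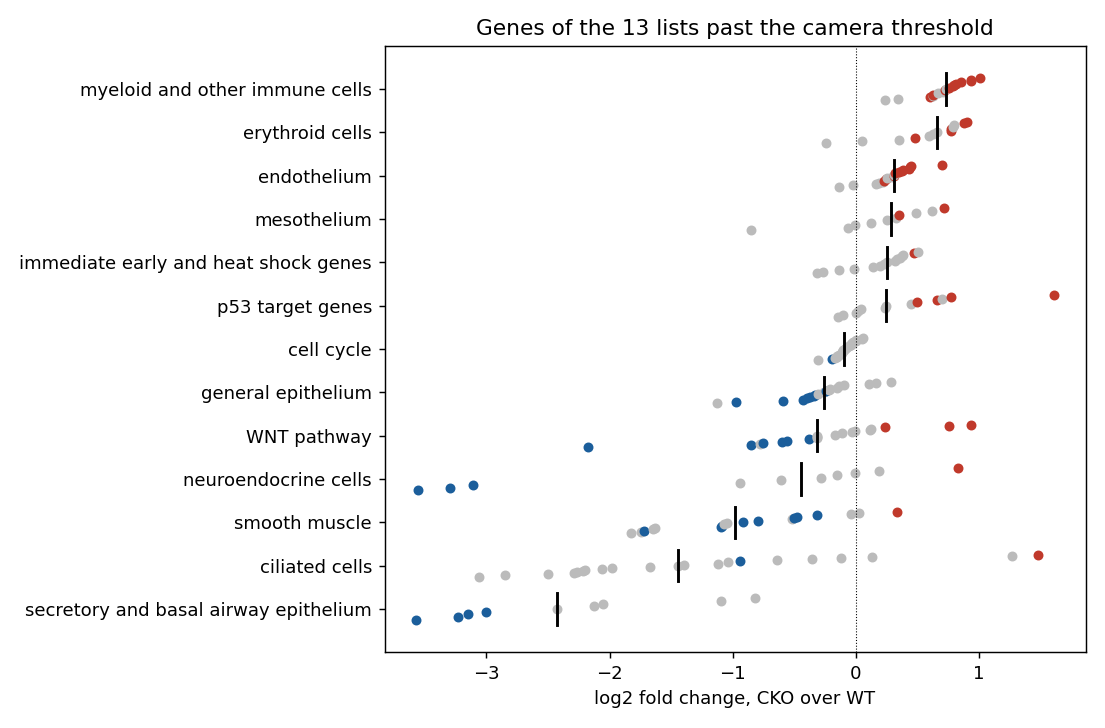
Log2 fold change (CKO over WT) of each tested gene of the 13 lists that passed camera with a preset correlation; red points rose, blue points fell, grey points did not pass, and black bars are list medians. The median of the secretory and basal airway list is -2.43, that of the smooth muscle list -0.98 and that of the myeloid list 0.73.

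Genes of the WNT pathway fell more often than they rose. Of 19 tested members 3 rose, 6 fell and 10 did not pass; adjusted over the list alone, 3 rose and 9 fell (camera adjusted p = 0.0407 for a fall, adjusted p = 0.520 with an estimated correlation). Wnt2 fell, as did the transcription factor gene Tcf7 (1.48-fold) and the pathway target Axin2 (1.30-fold from 71.8 ± 2.42 CPM). Apcdd1, a WNT inhibitor gene, rose 1.69-fold, and Wnt2b and Dkk3 rose 1.92-fold and 1.18-fold (the last 2 named after their values were seen). The list did not pass without WT replicate 1 (adjusted p = 0.0772, the highest with 1 lung left out). Its calls were 2 higher and 3 lower without WT replicate 1, 2 and 1 without WT replicate 2, and 1 and 2 without CKO replicate 2.

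Genes of the bone morphogenetic protein (BMP) pathway went both ways, and the list did not pass. Of 20 tested members 6 rose, 2 fell and 12 did not pass; adjusted over the list alone, 8 rose and 5 fell (camera adjusted p = 0.60). The ligand genes Bmp2, Bmp4 and Bmp7 rose 3.03-fold, 1.96-fold and 2.33-fold, Bmp7 from 17.1 ± 1.99 to 39.8 ± 5.99 CPM, and the signal transducer Smad9 and the target Id1 rose 1.73-fold and 1.47-fold. Those that fell were the receptor gene Bmpr1b (1.86-fold) and Bambi (1.36-fold), both named after their values were seen. With WT replicate 1, WT replicate 2, CKO replicate 2 or CKO replicate 3 left out, 2, 1, 3 and 4 members rose and 0 or 1 fell. Leaving out CKO replicate 1 gave 8 that rose and 6 that fell, and leaving out WT replicate 3 gave 6 and 4.

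In the Hedgehog pathway list, 12 genes were tested, of which 2 rose, 3 fell and 7 did not pass; adjusted over the list alone, 2 rose and 3 fell (camera adjusted p = 0.893). The receptor gene Ptch1, which is also a pathway target, rose 1.45-fold to 492 ± 58 CPM, and Hhip, another target, and the co-receptor genes Boc and Gas1 fell 2.12-fold, 1.44-fold and 1.36-fold, Gas1 named after its value was seen. Of 13 tested genes of the fibroblast growth factor (FGF) pathway 4 fell and 9 did not pass; adjusted over the list alone, 5 fell (camera adjusted p = 0.133). The receptor genes Fgfr1 and Fgfr2 fell 1.43-fold and 1.63-fold, as did the pathway targets Etv4 and Etv5; Fgfr2 overlaps several genes in the annotation used, so its value is uncertain. Of 13 tested Notch genes 2 rose, 3 fell and 8 did not pass, and adjusted over the list alone 2 rose and 3 fell (camera adjusted p = 0.893). Notch2 and the target Hey2 fell 1.57-fold and 2.26-fold, as did Jag1 (1.45-fold, named after its value was seen), and the ligand genes Jag2 and Dll4 rose 1.27-fold and 1.18-fold. The Notch list's median log2 fold change, 0.01, and its mean, -0.11, differed in sign, and camera pointed lower. Of 7 tested YAP/TAZ target genes 1 rose and 6 did not pass; adjusted over the list alone, 2 rose and 1 fell (camera adjusted p = 0.759). The kinase gene Lats2 rose 1.28-fold; the list's median was -0.01 and its mean 0.05, and camera pointed higher.

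Targets of p53 rose in part. Of 13 tested members 4 rose and 9 did not pass; adjusted over the list alone, 7 rose (camera adjusted p = 0.00599, adjusted p = 0.520 with an estimated correlation). Eda2r, a death receptor family gene, rose 3.04-fold from 2.45 ± 0.197 CPM, Gadd45a 1.71-fold, the apoptosis gene Bbc3 1.41-fold and the cell cycle inhibitor gene Cdkn1a 1.58-fold; Gadd45a overlaps E230016M11Rik. Without CKO replicate 2 or WT replicate 2, 1 rose, and without WT replicate 1 or CKO replicate 3, 2 rose.

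Cell cycle genes were lower as a list. Of 24 tested members 1 fell and 23 did not pass (4 were under an unadjusted p of 0.05); adjusted over the list alone, 0 fell in edgeR's test, and over all genes DESeq2 called 2 and limma-voom 0. The list passed camera (adjusted p = 0.0206, adjusted p = 0.784 with an estimated correlation). Plk1, a mitotic kinase gene, fell 1.14-fold from 108 ± 4.63 to 94.4 ± 3.20 CPM (adjusted p = 0.0499), and Ccne1 had CPM 52.1 ± 5.87 in WT and 42.0 ± 3.28 in CKO lungs (adjusted p = 0.0848). The list did not pass without WT replicate 1 (adjusted p = 0.143, the highest with 1 lung left out), WT replicate 2 (0.0643) or CKO replicate 3 (0.130). Nor did it pass with replicates 2 and 3 only or with the share of reads outside annotated features as a covariate. Both of those tests were chosen after the data were examined.

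Of 15 tested immediate early and heat shock genes, which respond to handling of tissue among other stimuli, 1 rose and 14 did not pass; adjusted over the list alone, 4 rose (camera adjusted p = 0.0441, adjusted p = 0.570 with an estimated correlation). Dusp1, a phosphatase gene, rose 1.39-fold, with Ergic1 overlapping it, and Egr1 had CPM 19.0 ± 2.15 in WT and 24.4 ± 2.48 in CKO lungs (adjusted p = 0.0838). The list did not pass without WT replicate 1 (adjusted p = 0.0594), WT replicate 2 (0.0672), WT replicate 3 (0.0630), CKO replicate 2 (0.0606) or CKO replicate 3 (0.0918), nor with total count scaling (0.0530). Of 15 tested genes of hypoxia and glycolysis 1 fell and 14 did not pass; adjusted over the list alone, 1 rose and 1 fell (camera adjusted p = 0.444). Hexokinase 2, Hk2, fell 1.40-fold from 63.9 ± 5.12 CPM, and Vegfa had CPM 207 ± 4.73 in WT and 233 ± 7.06 in CKO lungs (adjusted p = 0.0527).

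Nr1h5 stood with a small set of genes that were on in some lungs and off in others. A gene was counted as on at 20% or more, and off under 5%, of its highest lung, where that lung had at least 5 CPM and the gene lay on neither X nor Y; this rule and the genes it gives were chosen after values were seen. Of 27 such genes, 3 were on in every WT lung and off in every CKO lung: Nr1h5 and the pseudogenes Gm3608, with CPM 11.5 ± 0.516 in WT and 0.432 ± 0.0963 in CKO lungs, and Gm6969, with CPM 7.96 ± 0.398 in WT and 0.187 ± 0.0717 in CKO lungs. Of the others, 2, AI506816 and Gm7125, were off in replicate 1 of both groups and on in the other lungs, and so also split within WT. Another 13 split within the CKO lungs alone. The remaining 9 were on in some WT lungs and off in other WT lungs without following replicate 1, 7 of them processed pseudogenes. Among these, Rps13-ps1 had 0, 46.2 and 41.9 CPM in the WT lungs and 92.7, 0 and 0.0238 CPM in the CKO lungs. Within 5 Mb of Nr1h5, 19 of 114 tested genes were called (16.7%, against 8.71% of all genes tested), within 5 Mb of Gm3608, 3 of 15 (20%), within 5 Mb of Gm6969, 3 of 36 (8.33%), and within 5 Mb of Tgfbr2, 5 of 71 (7.04%). Each window includes the gene it is centred on, and Nr1h5, Gm3608 and Gm6969 are themselves among the genes called.

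**Figure D3:**
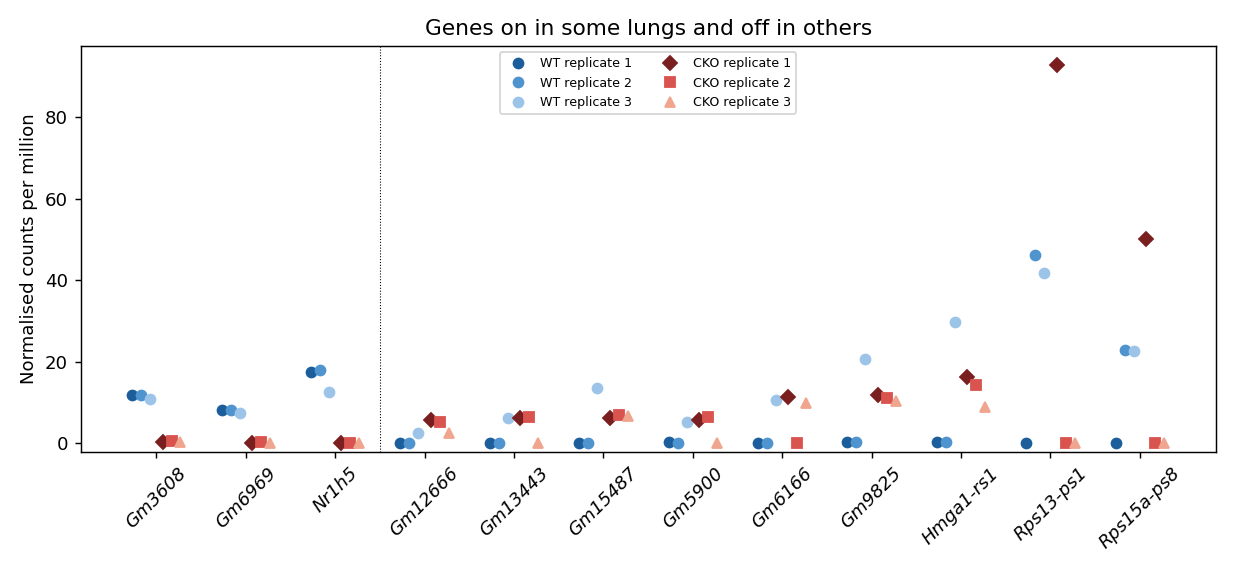
Normalised CPM in each lung of the 3 genes on in all WT and off in all CKO lungs (left of the dotted line) and of 9 genes on in some WT lungs and off in others (right). The 2 genes off in replicate 1 of both groups are not drawn. Circles are WT lungs and diamonds, squares and triangles CKO replicates 1, 2 and 3.

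The authors' deposited table gives the same direction for most genes. It holds 19683 genes, of which 2371 have an adjusted p under 0.05, 1369 higher and 1002 lower in the CKO lungs. The authors' deposited table calls 1277 of the genes called here, 82.1% of them, with 0 of opposite sign, and over the genes in both the sign was shared by 98.9%. The rest of the authors' 2371 calls were not called here, among them Foxj1 (log2 fold change -2.52, adjusted p = 0.00255 in the authors' edgeR fit). Both fits rest on the same lungs, so the shared signs are not independent support. For Tgfbr2 the authors' deposited table has a log2 fold change of 0.09 (adjusted p = 0.799) and for Nr1h5 of -7.83.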

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

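The tests with replicate 1 as a covariate, with replicates 2 and 3 only and with the no-feature share as a covariate were chosen only after the result was seen. Of the counts of genes past the threshold, 1006 higher and 549 lower, those that moved by over 1.5 times were these. The lower count was 884 with no low-count filter, 991 with DESeq2 and 1051 with replicates 2 and 3 only. Limma on log2(RPKM + 1) gave 489 and 331, limma on log2(RPKM + 0.1) gave 521 and 332, and the test against a fold change of 1.2 gave 307 and 135. Leaving out 1 lung at a time gave 162 to 1713 higher and 90 to 1185 lower. Of these fits, the one without WT replicate 3 (1246 and 813) stayed within 1.5 times. A fit with 5 lungs has fewer residual degrees of freedom, but this alone does not account for the counts that fell. Replicates 2 and 3 only, with fewer lungs still, gave 1363 and 1051, and leaving out CKO replicate 1 gave 1713 and 1185. The fits with 1 lung left out whose counts fell all kept CKO replicate 1. Beyond this the cause was not tested. The other 10 alternatives stayed within 1.5 times for both counts, among them replicate 1 as a covariate (1195 and 778) and the no-feature share as a covariate (743 and 481, with 1109 of the 1555 calls kept). In none of the 22 alternatives did a called gene change sign.

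Tgfbr2 did not pass in any alternative. With the no-feature share as a covariate the folds of 9 of the 12 largest rises moved by over 1.5 times, to log2 fold changes of 5.44 for Dkk1, 5.09 for Pax7, 4.25 for Irx6, 3.77 for Pdyn, 2.37 for Scin, 3.05 for Isl1, 2.83 for Elfn1, 2.61 for Myh7b and 2.49 for Myh8. Limma-voom moved Dkk1 (6.24), Pax7 (6.08), Scin (3.23), Krt15 (-4.29), Cyp2f2 (-3.74) and Upk3a (-4.64). With replicates 2 and 3 only, 13 named genes moved as much, all to larger changes, Krt15 and Upk3a the most (-5.34 and -6.74). For the other 156 named genes, 3390 values were computed over the 22 alternatives: 2842 stayed on their side of the threshold, 423 lost their call, 125 gained one and 0 reversed, while 25 values of genes not called changed sign. The 13 lists that passed camera fell to 0 with an estimated correlation, which by construction allows for the correlation between genes of a list, and numbered 10 to 17 with 1 lung left out, 16 with replicate 1 as a covariate, 15 with replicates 2 and 3 only and 13 with the no-feature share as a covariate or total count scaling. With replicates 2 and 3 only the WNT and cell cycle lists did not pass (adjusted p = 0.121 and 0.106) and with the no-feature covariate the cell cycle and immediate early lists did not (0.0801 and 0.0613), where ranges with 1 lung left out were 0.0214 to 0.0772 for WNT, 0.000658 to 0.143 for cell cycle and 0.0258 to 0.0918 for immediate early genes. The TGF-beta target list, which did not pass with all lungs (0.0526, and 0.0124 to 0.179 with 1 lung left out), passed with total count scaling (0.0366), replicate 1 as a covariate (0.0472), the no-feature covariate (0.0126) and replicates 2 and 3 only (0.00956). Replicate 1 as a covariate also gave 0.04001 for pericytes and for neurons and Schwann cells, and replicates 2 and 3 only gave 0.00967 for cartilage, 0.0316 for lipofibroblasts and 0.0346 for neurons and Schwann cells, where ranges with 1 lung left out were 0.0136 to 0.143 for pericytes, 0.0124 to 0.377 for cartilage and 0.0249 to 0.172 for lipofibroblasts. The FGF list passed with the no-feature covariate only (0.0182, where leaving out 1 lung gave 0.0542 to 0.620).

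The replicate numbers were not taken to pair the lungs: correlations of same-numbered lungs were 0.102, 0.0887 and 0.0365, each WT lung correlated best with its own number and not each CKO lung did, although AI506816 and Gm7125 (named after their values were seen) were off in replicate 1 of both groups. The replicate block gave 1087 higher and 693 lower genes, 13 lists, and an adjusted p of 0.0526 for mesothelium and 0.0440 for neurons and Schwann cells (0.00220 to 0.0769 and 0.0225 to 0.546 with 1 lung left out). In the simulation 6 of 43 changed genes with a mean under 1 CPM were recovered, against 123 of 157 with a mean of at least 1 CPM; that split was made after the results were seen.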

Other observations

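All tests of explanations reported here were chosen only after the results they concern were seen, except the count of lists over other splits of the lungs, and the on and off rule was changed after its results were seen.

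Genes of fluid and ion transport, which in the fetal lung move liquid into and out of the airspace, went both ways. Of 12 tested members 2 rose, 2 fell and 8 did not pass; adjusted over the list alone, 2 rose and 4 fell (camera adjusted p = 0.714). The subunit genes Scnn1b and Scnn1g of the epithelial sodium channel fell 3.30-fold, from 8.14 ± 0.592 CPM, and 2.20-fold, from 13.9 ± 0.324 CPM, while the chloride channel gene Ano1 and the water channel gene Aqp1 rose 1.5-fold and 1.48-fold; Scnn1b overlaps Cog7 and had a log2 fold change of -2.52 without CKO replicate 1, against -1.72 with all lungs, and did not pass without any other 1 lung (adjusted p = 0.121, 0.152, 0.0702, 0.165 and 0.122 without WT replicates 1, 2 and 3 and CKO replicates 2 and 3). No member of this list passed without WT replicate 1, WT replicate 2, CKO replicate 2 or CKO replicate 3. In the retinoic acid pathway, of 10 tested genes 2 rose, 1 fell and 7 did not pass; adjusted over the list alone, 3 rose and 3 fell (camera adjusted p = 0.911). The retinaldehyde dehydrogenase gene Aldh1a3 rose 4.04-fold from 1.25 ± 0.0997 CPM and the binding protein gene Crabp1 rose 2.62-fold.

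Genes of neighbouring tissues gave few calls. Of 18 tested cardiac and skeletal muscle genes 1 rose and 17 did not pass; adjusted over the list alone, 2 rose and 1 fell (camera adjusted p = 0.919). Myh8 rose 8.84-fold, and the cardiac actin gene Actc1 had CPM 47.2 ± 1.73 in WT and 19.1 ± 12.1 in CKO lungs (adjusted p = 0.0707). The median of this list was -0.09 and its mean 0.15 (log2), and camera pointed lower. Of 14 tested genes of neurons and Schwann cells 1 fell and 13 did not pass; adjusted over the list alone, 1 fell (camera adjusted p = 0.174, and 0.0225 without CKO replicate 1, the lowest of 0.0225 to 0.546 with 1 lung left out). That gene was Ret, at 4.70-fold, and Erbb3, a Schwann cell receptor gene, had CPM 108 ± 12.3 in WT and 89.4 ± 7.50 in CKO lungs (adjusted p = 0.114). Of 5 tested genes of thyroid, thymus and liver, 7 mitochondrially encoded genes and 5 sex-specific genes, 0 were called by edgeR, DESeq2 or limma-voom, over all genes or, for edgeR, adjusted over the list alone, and 0 were under an unadjusted p of 0.05 (camera adjusted p = 0.893, 0.893 and 0.973). Medians and means were 0.13 and -0.03 (log2) for thyroid, thymus and liver, where camera pointed higher, and 0.06 and 0.11 for the sex-specific genes, where it pointed lower. Alb had CPM 1.10 ± 0.687 in WT and 0.613 ± 0.283 in CKO lungs, mt-Nd1 CPM 3211 ± 306 in WT and 3051 ± 23.7 in CKO lungs and Xist CPM 659.8 ± 1142 in WT and 837 ± 1449 in CKO lungs.

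The first pattern is that airway lists were lower while immune, vessel and blood lists were higher in the CKO lungs. A lower share of all epithelial cells would lower proximal and distal lists alike, but the median of the 9 secretory and basal genes lay -2.37 (log2) from that of 30 distal tip, type 2 and type 1 genes (permutation p = 3e-05, 2-sided, across genes, which are not independent replicates). A lower share of the main cell type, with the others passively enriched, would raise other types alike, but the median of the 17 myeloid genes lay 0.432 above that of 40 endothelial, pericyte and mesothelial genes (permutation p = 2e-05, 2-sided, across genes). The lists were compared after their medians were seen, so these p-values decide nothing by themselves. The general epithelium list was left out of the first comparison. Of its 19 tested members 8 fell and 0 rose, with a median of -0.257, a direction that a lower share of epithelial cells would also give. The erythroid list, with a median of 0.66, was left out of the second comparison, and many marker genes are made by more than 1 cell type. These lists did not move alike, which argues only against a uniform shift of all such markers as the whole cause. A lower share of a cell type as part of the cause, a change in single cell types or a change in expression within cells stay open, as hypotheses that may account for the pattern. Whole-lung counts do not part these, and no cell counts were analysed here.

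The second pattern is that CKO replicate 1 lay between the WT lungs and the other CKO lungs. Its share of reads outside annotated features was the highest of the 6. Slopes were taken over 270 autosomal genes in which it differed at least 2-fold from the other CKO lungs, chosen without the WT lungs. The change per percent of that share among the WT lungs followed the change per percent among the CKO lungs with a slope of -0.251. This slope was -0.363 to -0.152 for pairs of WT lungs, whose shares span 1.57 percentage points. The deviation of WT replicate 1 followed that of CKO replicate 1 with a slope of -0.0705 over the same genes. These slopes argue only against a share, or a difference of replicate 1, that acts alike in both groups. Genes near 0 in the WT lungs, such as Scin at 0.253 to 0.288 CPM, could hardly show either. An effect of the share or of sex that acts in the CKO lungs alone stays open, since CKO replicate 1 was also the only female CKO lung. A smaller share of changed cells would move all genes by 1 fraction: the 108 genes that fell at least 4-fold without it moved by a median of 53.7% (interquartile range 0.212 as a fraction, with a bound of 0.894 set at 1.5 times that of a WT lung), and the 80 that rose by 40.4% (0.464, with a bound of 0.527 set from CKO replicates 2 and 3). Fractions spread evenly from 0 to 1 would stay within both bounds, so these values decide nothing and a smaller share of changed cells stays open. Single genes differed widely: Wnt2, which changed less than 4-fold, moved by 103%, Dkk1 by 8.25% and Scin by 1.59%. These 3 were picked from among others, and no range was set for the fraction of a single gene, so they decide nothing either. The test on rising genes was added after that on falling genes came out.

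The third pattern is that Nr1h5, Gm3608 and Gm6969 were on in every WT and off in every CKO lung. Sequence variants that differ between the animals may account for this. That none of the 3 splits within a group follows from how they were picked, so it decides nothing. Other genes did split within WT, 9 without following replicate 1 and also AI506816 and Gm7125. AI506816 and Gm7125 were off in replicate 1 of both groups, the female lungs, so they also follow sex. No genotype or read sequence was examined, so these splits do not show whether the animals differ in sequence. Gm9825 had 0.288, 0.253 and 20.8 CPM in the WT lungs and 11.8, 11.1 and 10.4 CPM in the CKO lungs. Such graded levels were not seen in all 9: Gm13443 lay at 6.13 to 6.37 or 0.064 to 0.175 CPM. Called genes were 16.7% of those tested within 5 Mb of Nr1h5, 20% for Gm3608 and 8.3% for Gm6969, against 8.7% of all. Each share includes the gene itself, which was chosen for its change, so it overstates the share of the neighbours. These shares were not tested. Whether variants or the targeting of Tgfbr2 caused the pattern of the 3 genes cannot be told apart, because they follow the groups exactly. The rule at first compared lungs by a fixed fold, and was then restricted to genes on and off within WT because it had taken in airway genes that are low in CKO replicates 2 and 3.

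With 10 splits of the 6 lungs into groups of 3, no result can have a share under 0.05. Each other split also mixes WT and CKO lungs within a group. A real group difference then widens the spread and lowers the calls, so counts from those splits are no baseline for chance. The real split is the 1 split of the 10 that gave as many genes higher (1006, highest other 2), as many genes lower (549, highest other 2, the larger direction of each other split being taken for both counts, since a split and its mirror are one) and as many lists (13, highest other 10).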
